A study of Mus musculus with 2 samples.

How the data were processed

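Pancreatic islets were compared between PERK wild-type and PERK knockout mice 2 days after birth. PERK, encoded by Eif2ak3, is a kinase of the endoplasmic reticulum (ER) that phosphorylates the translation initiation factor eIF2 alpha when unfolded protein accumulates. Per the labels' protocols, islets were isolated by collagenase P digestion, total RNA was purified on RNeasy columns, and biotin-labelled cRNA was made and hybridised to Affymetrix mouse 430A arrays, which carry sets of short oligonucleotide probes for each transcript. There was 1 array per genotype, the wild-type label gives mixed strains and mixed sexes, and whether islets of several pups were pooled is not given in the sources used here.

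The authors deposited a linear signal intensity per probe set for both arrays. GCOS 1.02, Affymetrix's operating software, is the only tool in the submitters' processing notes. The background correction, the summary method and the detection calls are not given in the sources used here. The deposited intensities of the 22690 probe sets had a 2% trimmed mean of 150.1 on both arrays, so both had been scaled to a common target before deposit. The median intensity was 58.45 on the wild-type array and 62.6 on the knockout array, and the maxima were 8133 and 8242. A signal of 0 was listed for 2 probe sets of the wild-type array and for 0 of the knockout array.

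From these values, both arrays were set to the same 2% trimmed mean (factor 1.00 for the knockout array). Signals under the 40th percentile of both arrays together (39.8) were set to that floor, and log2 knockout over wild type was taken. A gene above the floor on both arrays was called measured. A gene above it on only 1 array has a bound ("at least N-fold"), and a gene at the floor on both has no fold. Probe sets were named from the platform's gene annotation: 20393 had 1 gene symbol, 691 had several, 1542 were unnamed here and 64 were Affymetrix controls. Of the entries with 1 symbol, 20364 matched a gene in the RefSeq gene table of GRCm38.p6, and 0 symbols changed through it. Each of the 12393 genes was represented by its brightest probe set. Of these, 8133 were measured, 693 had a bound and 3567 were at the floor. No genome build is given for the array annotation, so no coordinates are reported.

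With 1 array per genotype there is no spread between replicates, and no p-value was computed. Genes were counted by size, at least 2-fold higher or lower. The measure of error used here is the disagreement between probe sets of a gene: the SD of the difference between the log2 ratios of a gene's 2 brightest measured probe sets, divided by the square root of 2, over 2597 genes. It covers probe and hybridisation error, not animals, litters or RNA preparations. The number of arrays limits the precision of every value.

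A total of 34 gene lists were fixed before the data were examined, together with the design, the alternatives and the rule for named genes. For each list the median log2 ratio of the measured members was set against 10000 random lists of the same size, matched on mean signal in 20 brightness bins, and its percentile was recorded. A median under the 2.5th or over the 97.5th percentile is called outside the random range below. By chance 1.7 of the 34 lists would lie there. The percentile describes these 2 libraries: members of a list vary together, so it is not a test of genotype.

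Named genes are Eif2ak3; the 12 highest and 12 lowest ratios among measured genes at or above the 75th percentile of gene signals (218.0) on the brighter array; the 3 largest bounds in each direction above that signal, of which there were none; in each list up to 4 members at least 2-fold apart in each direction, joined by the 2 brightest members where fewer than 2 were that far apart; and all islet hormones and beta cell transcription factors. Other genes are said to have been chosen after their values were seen.

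The procedure was tested on simulated data made from the wild-type array and the observed probe set differences, over 20 simulations of the table of 12393 genes. In each, 200 changed genes were drawn from the 8133 measured ones, with all probe sets of a gene changed alike. The procedure called 89.6% of 4-fold and 88.45% of 3-fold changes at the 2-fold limit. These shares do not cover genes with a bound or at the floor, or genes whose probe sets respond differently. With no gene changed, it gave a mean of 7.45 measured genes higher (at most 12) and 4.70 lower (at most 10). The simulated noise was probe set disagreement only, so these counts leave out differences between animals, litters or RNA preparations. All 20 simulated lists of 20 genes shifted by -0.50 fell under the 2.5th percentile. Alternatives were the deposited scale, median centring, quantile and loess normalisation, floors at the 25th and 60th percentiles, a pseudocount in place of the floor, the median over a gene's probe sets, leaving out probe sets of the _x_at and _s_at types, counting only members on a single list, and limits of 1.5-fold and 3-fold. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used.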

Results

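Gene expression in pancreatic islets was measured on 2 Affymetrix mouse 430A arrays, 1 for wild-type and 1 for PERK knockout mice, both at 2 days after birth. The design poses the question of how loss of PERK alters transcript levels in neonatal islets. There were no replicates, so each value below is a single array signal in arbitrary intensity units and each ratio compares these 2 libraries. Across the 8133 genes measured on both arrays, the log2 signals correlated with a Pearson r of 0.973, across genes, which are not independent replicates. The median log2 ratio of knockout over wild type was 0.03. Of all measured genes, 45.1% had a log2 ratio below 0, called below equality here. Counts above or below equality are to be read against this share, not an even split. Probe sets of the same gene disagreed by 0.26 on the log2 scale (SD per probe set), with 0.19 among the brightest 649 of 2597 genes and 0.25 to 0.29 among the others.

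The targeted gene was lower in the knockout library. Eif2ak3, which encodes PERK, had a signal of 117.7 in the wild type and 58.7 in the knockout on its brightest probe set, 2.01-fold lower. Its other 2 probe sets were at the floor on both arrays. Which exons the knockout removes is not given in the sources used here, and a probe set outside the deleted part would check nothing about the labels. Control transcripts added at hybridisation differed by a median of 0.06 on the log2 scale over 18 probe sets (SD 0.27). The 27 unspiked bacterial control probe sets stayed under the floor on both arrays. The 3' over 5' signal ratio of beta-actin, a measure of cRNA length, was 1.61 in the wild type and 2.01 in the knockout, and that of Gapdh was 1.01 and 0.867.

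S100a8, S100a9 and Ngp, genes of myeloid white blood cells, had the highest ratios among brightly measured genes, and 13 of the 53 measured genes at least 2-fold lower were on the cell cycle lists. At least 2-fold differences were found for 53 measured genes that were lower and 42 that were higher in the knockout. A further 3 genes (Hmmr, Sytl1 and E2f8, named after their values were seen) were lower and 11 were higher as bounds, with the other array at the floor. The totals of 53 higher and 56 lower became 38 and 64 with quantile normalisation and 37 and 64 with loess. With no gene changed, simulated arrays gave means of 7.45 higher and 4.70 lower measured genes. Those arrays held probe set error only, with no difference between animals, litters or RNA preparations. They therefore do not give the counts to be found between preparations of the same genotype. The largest ratios among measured genes were those of S100a8 (98.9 to 788.8, 7.98-fold higher) and S100a9 (120.8 to 778.3, 6.44-fold), which encode the subunits of calprotectin in neutrophils and monocytes, and of Ngp (87.3 to 420.6, 4.82-fold), a neutrophil granule protein. Next among genes with a signal of at least 218.0 on the brighter array were Dusp26 (3.25-fold), Acaa1a (2.79-fold), Csnk2a2 (2.70-fold), Rps27 (2.51-fold), Ramp1 (216.5 to 541.0), Ang (2.44-fold), Mmp2 (2.43-fold), Lyz1 (2.42-fold) and Rab3b (2.21-fold). Among genes under that signal, and named after their values were seen, Lcn2, a neutrophil granule protein, was 3.87-fold higher (48.3 to 186.8), Vmn1r44 2.91-fold and Reg2 2.56-fold.

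Among the genes lower in the knockout, Npy, a neuropeptide also made in islets, went from 1027 to 304.8 (3.37-fold lower). Pcsk1, the prohormone convertase that cleaves proinsulin, went from 919.8 to 332.6 (2.77-fold lower). Others encode parts of the cell division machinery: Spc25 of the kinetochore (906.2 to 303.2, 2.99-fold lower), cyclin A2 Ccna2 (2.88-fold), Ube2c (2.75-fold), Birc5 (2.67-fold), the mitotic kinase Cdk1 (539.6 to 203.4, 2.65-fold), Rrm2 (2.65-fold) and Mki67 (236.9 to 89.6, 2.64-fold). Asb6 (5.99-fold lower), Hip1r (4.66-fold) and Cklf (2.82-fold) completed the 12 lowest. Several of these ratios rest on a single probe set. A second measured probe set gave a log2 ratio of 0.50 for Asb6 against -2.58 on the brightest, the 2 others of Hip1r gave 0.00 and 0.28, and the 3 others of Csnk2a2 lay between -0.07 and 0.13. The 3 others measured for Cklf lay between -0.54 and 0.17. The other of Mmp2 gave 0.27, that of Lyz1 0.32 and that of Acaa1a 0.72. Those of Ccna2 (-1.12) and Rrm2 (-1.46 and -0.37) were lower again. Of 13 lower genes with a second measured probe set, 9 had the same direction on it and 3 were again at least 2-fold lower. Of 13 higher genes, 12 had the same direction and 0 were again 2-fold higher.

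**Figure D1:**
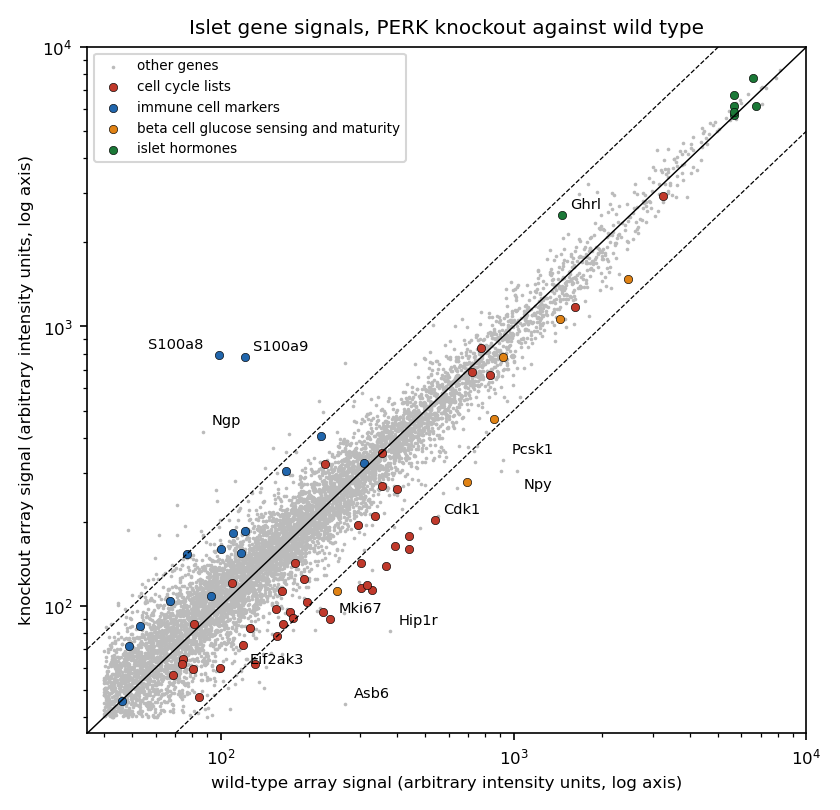
Signal of each of the 8133 genes measured on both arrays, wild type (x axis) against PERK knockout (y axis), in arbitrary intensity units on log axes, with 1 point per gene, the solid line at equal signals and dashed lines at 2-fold. S100a8, S100a9 and Ngp lie above the upper dashed line and many cell cycle genes (red) lie near or below the lower one, and all islet hormones but Ghrl sit at the top of the signal range, where differences can be compressed.

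Cell cycle transcripts were lower as a group. Of 18 measured genes of G2 and mitosis, 17 were below equality and 10 were at least 2-fold lower, with a median log2 ratio of -1.04 (2.06-fold lower), under the median of all 10000 random lists. A further 8 members were at the floor in the knockout only, among them Hmmr, the hyaluronan-mediated motility receptor, at least 2.65-fold lower. With these at their bounds the median was -0.88. The exception was Foxm1, a transcription factor of mitotic genes named after its value was seen, at 0.08. Of 24 measured genes of G1 and S phase, 21 were below equality and 3 were at least 2-fold lower: Rrm2, the replication helicase subunit Mcm2 (438.6 to 177.8, 2.47-fold, with -0.40 on its second probe set) and Uhrf1 (2.10-fold). Their median was -0.44, again under all random lists. D-type cyclins, named after their values were seen, were not among the lower genes by size: Ccnd1 had a log2 ratio of 0.11, Ccnd2 of -0.15 and Ccnd3 of 0.50. Over both lists, 13 of 42 measured genes were among the 53 lower genes, against 0.27 expected from their share of measured genes. The 14 measured cell cycle inhibitors had a median of -0.08 (8.14th percentile) with none at 2-fold, and Btg1 and Btg2, antiproliferative factors, had log2 ratios of 0.20 and 0.01. The 13 measured apoptosis genes had a median of 0.01 with none at 2-fold, with Cycs (cytochrome c) at -0.29 and Mcl1, an anti-apoptotic BCL2 family member, at -0.08.

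Genes of beta cell glucose sensing and maturity were lower, and no measured hormone gene was 2-fold apart. The 7 measured hormone genes had a median log2 ratio of 0.12 (93.95th percentile). Ins2, the insulin gene named on this array, went from 5652 to 6163, Gcg (glucagon) from 5662 to 5718, Sst (somatostatin) from 5645 to 5868, Ppy from 6573 to 7733, Pyy from 5654 to 6747 and Iapp (amylin) from 6710 to 6149. Ghrl (ghrelin) had the largest ratio of the list, from 1461 to 2503 (1.71-fold higher). All but Ghrl had signals of 69.4% to 93.8% of the maximum of their array, where a difference can be compressed. A dimmer probe set of Iapp went from 410.5 to 442.8 (log2 0.11), and its 2 others gave -0.07 and -0.18. All 6 measured genes of glucose sensing and maturity were below equality, with a median of -0.81 (1.75-fold lower), under all random lists. Sytl4 (granuphilin), an insulin granule protein, was 2.49-fold lower and the cation channel Trpm5 2.21-fold lower. The glucose transporter Slc2a2 (860.4 to 464.9, 1.85-fold) and the glucose-6-phosphatase subunit G6pc2 (2459 to 1483, 1.66-fold) were named after their values were seen. Beta cell transcription factors had a median of -0.15 over 10 measured genes (6.41st percentile) with none at 2-fold. Their log2 ratios were -0.58 for Nkx6-1, -0.57 for Insm1, -0.40 for Mnx1, -0.34 for Pdx1, -0.16 for Neurod1, -0.15 for Pax6, -0.01 for Nkx2-2, 0.02 for Hnf4a, 0.12 for Foxa2 and 0.33 for Isl1, and Pax4, Nkx6-2 and Rfx3 were at the floor on both arrays. The other measured probe sets gave 0.17 for Neurod1, 0.24 and -0.27 for Pax6, -0.09 and 0.21 for Hnf4a, and 0.19 for Isl1.

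The 5 measured members of the list of alpha and delta cell regulators were all above equality, with a median of 0.61 (1.53-fold higher, 99.98th percentile). The delta cell factor Hhex went from 313.0 to 479.2 (1.53-fold). Ttr, a carrier protein and not a regulator, was about level (8133 to 8242, log2 0.02). It had the brightest signal on both arrays, and its other probe sets gave -0.01 and 0.16. Pou3f4 (1.92-fold) and Irx2 (1.53-fold), both alpha cell factors, were named after their values were seen. Of 13 prohormone processing and granule genes, Pcsk1 alone was 2-fold apart, and the median was 0.07 while the mean was -0.06. The chromogranin genes Chga and Chgb had log2 ratios of -0.18 and -0.14. The 9 measured exocytosis genes had a median of 0.03 and a mean of -0.09, with Snap25 at 0.18 and Cplx2 at 0.19.

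**Figure D2:**
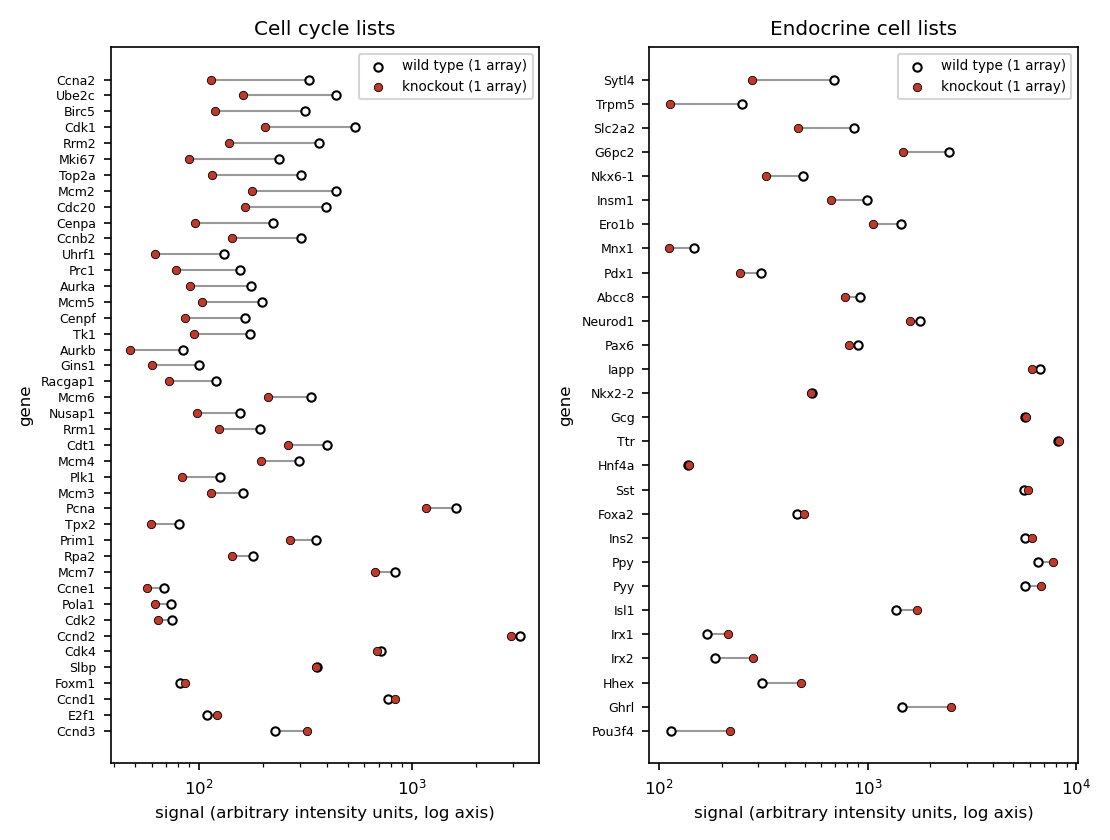
Signals in arbitrary intensity units on a log axis for genes measured on both arrays, with wild type as open circles, knockout as red circles and 1 array each. The left panel shows both cell cycle lists and the right panel the 4 endocrine lists. Signals of Cdk1 go from 539.6 to 203.4 and those of Slc2a2 from 860.4 to 464.9.

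On the lists for the unfolded protein response and eIF2-dependent signalling, the pathways in which PERK acts, no measured gene but Dnajb11 was 2-fold apart. Only 53 lower and 42 higher genes were found at that limit among all 8133, so this says little about the pathways. The 26 measured ATF4 and integrated stress response targets had a median of 0.00 (34.21st percentile), with 13 members on either side of equality. Atf4, the transcription factor translated when eIF2 alpha is phosphorylated, had a log2 ratio of -0.31 (-0.06 on its other measured probe set), and Slc3a2, an amino acid transporter subunit, of -0.19. Ddit3 (CHOP), named after its value was seen, had 0.65. ER chaperones and folding enzymes had a median of -0.14 over 22 genes (2.82nd percentile). The ER co-chaperone Dnajb11 went from 576.3 to 253.5 (2.27-fold lower), and Pdia3 had a log2 ratio of -0.26. Hspa5 (BiP) had 0.22 on its brightest probe set and -0.07 on its other. ER-associated degradation genes had a median of -0.07 over 15 genes, with Vcp at -0.31 and Selenos at -0.05. The ER stress sensors and transducers had a median of -0.08 over 11 genes, with Xbp1 at -0.02 (-0.36 to 0.11 on its other probe sets) and Tmbim6 at -0.04. Aminoacyl-tRNA synthetases had a median of -0.11 over 18 genes (4.25th percentile), with Gars at -0.16 and Sars at -0.01. The eIF2 kinases and initiation factors had a median of 0.02 over 15 genes, with Eif2s2 at -0.11 (0.04 to 0.81 on its other probe sets) and Eif5 at 0.02.

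The machinery that moves secretory proteins into and out of the ER was slightly lower across many genes. Of 25 signal peptide and translocation genes, 21 were below equality, with a median of -0.22 (1.16-fold lower, 0.04th percentile). The brightest were Ssr4 (-0.07, and -0.33 and 0.36 on its other probe sets) and Spcs1 (-0.14), subunits of the translocon-associated complex and the signal peptidase. Of 28 ER to Golgi trafficking genes, 22 were below equality, with a median of -0.22 (1.17-fold lower) under all random lists. The COPII GTPase Sar1a had a log2 ratio of -0.51 (1.42-fold lower) and the KDEL receptor Kdelr2 of 0.03, with -0.33 and -0.27 on their other probe sets. No measured gene of either list was 2-fold apart. Cholesterol and lipid synthesis genes had a median of -0.29 over 15 genes (1.22-fold lower, below all random lists), with Acly at -0.30 and Hmgcs1 at -0.29. That median was -0.12 (3.17th percentile) when taken over all probe sets of each gene.

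Markers of other cell types showed how the 2 islet preparations compared. Of 15 measured immune markers, 14 were above equality, with a median of 0.67 (1.59-fold higher, above all random lists). S100a8, S100a9 and the MHC class II gene H2-Aa (2.01-fold) were at least 2-fold higher, and the complement gene C1qc was at least 2.70-fold higher. The other measured probe set of H2-Aa gave a log2 ratio of 0.69. Pancreatic acinar enzymes were among the brightest transcripts of both libraries: Cela3b (elastase) went from 7279 to 7119 and Ctrb1 (chymotrypsinogen) from 7076 to 7178. These signals were 86.4% to 89.5% of the array maximum. The 23 measured acinar markers had a median of 0.08 (96.99th percentile) with none at 2-fold. Less bright members, named after their values were seen, had log2 ratios of 0.92 for Pla2g1b, 0.85 for Reg1, 0.69 for Ctrl, 0.67 for Zg16 and 0.46 for Cel, and of -0.44 for Ctrc and -0.29 for Spink1. Duct markers had a median of -0.00 and a mean of 0.16 over 11 genes. Tspan8 was 2.13-fold higher on its brightest probe set, with log2 ratios of 0.57 and 0.65 on its other measured ones. The keratins Krt8 and Krt18 had log2 ratios of 0.00 and 0.18. The 15 endothelial markers had a median of -0.10 (10.45th percentile), with Esam at -0.10 and Plvap at 0.08. Mesenchymal and matrix genes had a median of -0.19 over 22 genes (0.09th percentile), with 18 below equality, Sparc at -0.02 and Vim at -0.01. The 8 measured Schwann and neuronal markers had a median of 0.30 (98.37th percentile), with Nefm at 0.40 and Th at -0.26, and this list was outside the random range in 5 of 10 alternative settings. Red blood cell genes were measured for only 2 members, Tfrc and Alas2, both at -0.19. Of 6 measured fat, lymph node and liver markers, fibrinogen Fgb was 2.54-fold higher, and the median was 0.19, with Lpl at -0.02 and Fabp4 at 0.13. The other measured probe set of Fabp4 gave 0.67.

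The remaining lists concerned metabolism, handling and sex. Ribosomal protein genes had a median of 0.14 over 18 genes (99.78th percentile), with 17 above equality, Rplp2 at 0.08 and Rps14 at 0.02. With quantile normalisation that median was 0.05 (92.16th percentile). Oxidative phosphorylation genes had a median of -0.11 over 26 genes (9.18th percentile), with Cox7a2 at -0.14 and Ndufa1 at -0.30. Glycolysis genes had a median of 0.13 over 15 genes, with Aldoa at 0.09 and Pgk1 at -0.66, whose other 2 probe sets gave -0.31 and 0.30. Insulin and IGF signalling genes had a median of -0.03 and a mean of 0.02 over 18 genes, with Igf2 at 0.06 and Igfbp7 at -0.23, whose second probe set gave 0.10. Immediate early and stress response genes, which respond to tissue handling, had a median of 0.11 over 21 genes (94.94th percentile). Hspa1b was 2.06-fold higher on its chosen probe set and at 0.03 on another, Fos had a log2 ratio of -0.28 and Egr1 of 0.16. Hypoxia genes had a median of 0.07 over 10 genes, with Ndrg1 at 0.26 and Bnip3 at 0.29. The X-inactivation transcript Xist was 1.33-fold higher in the knockout (628.1 to 832.6), and the Y-linked Eif2s3y 1.48-fold lower (103.2 to 69.9).

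**Figure D3:**
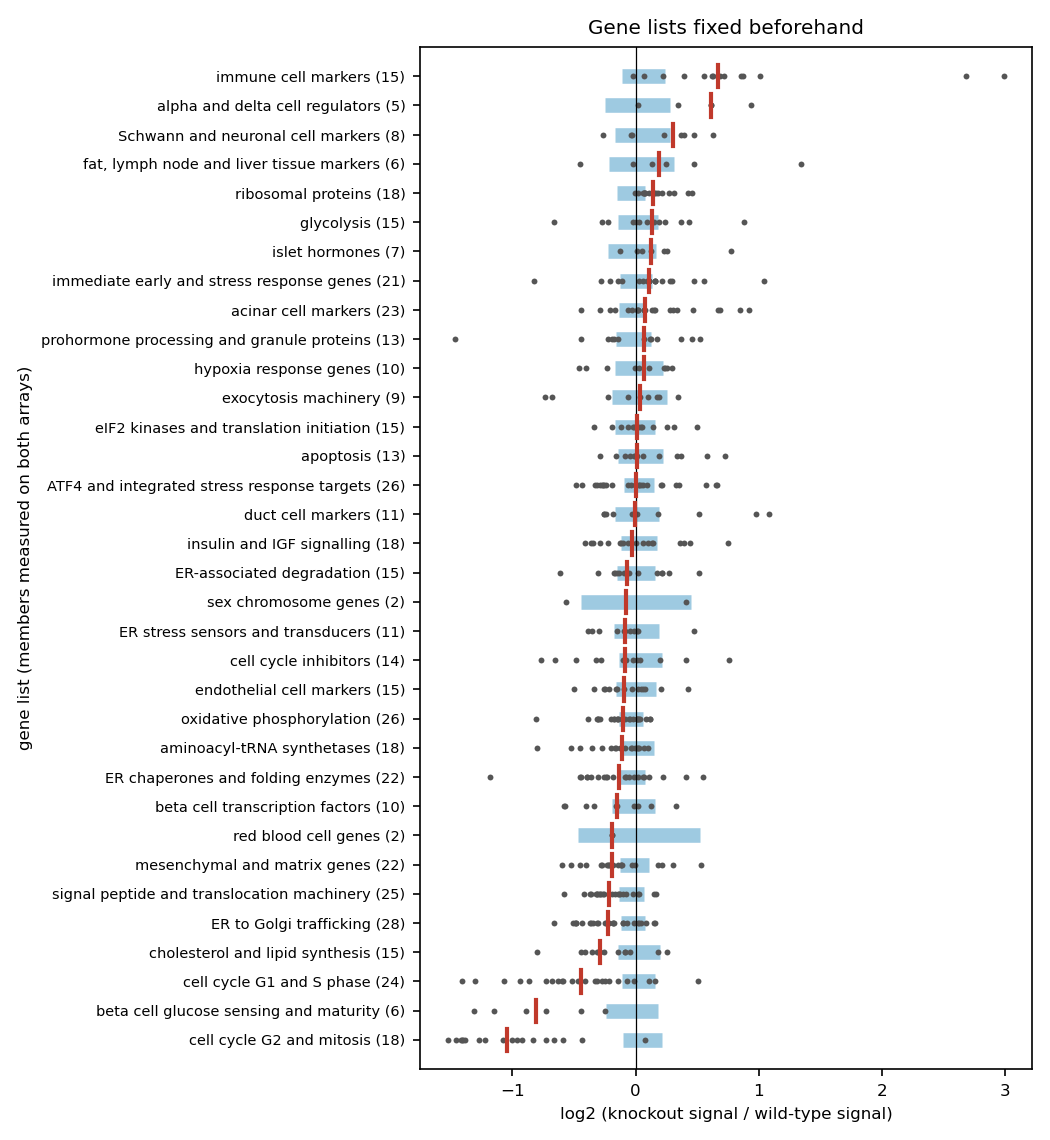
Log2 ratio of knockout over wild-type signal (x axis) for the 34 gene lists (y axis, number of measured members in brackets), with 1 grey point per gene, the list median as a red line and the central 95% of the medians of 10000 random matched lists as a blue bar. The median of the G2 and mitosis list lies at -1.04 and that of the immune markers at 0.67, both outside their blue bars.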

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

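Probe sets with no gene name or with several genes entered no comparison above, and 1006 of them were above the floor on both arrays. Of these, 8 drew attention because they were at least 2-fold higher in the knockout library than in the wild-type library, and 3 were at least 2-fold lower. Those with several genes had log2 ratios of 1.94 (40.2 to 153.8), 1.72 (43.8 to 144.7), 1.11 (185.0 to 399.9), 1.07 (1105 to 2322) and 1.07 (49.6 to 103.8). Those with no gene name had log2 ratios of 1.35 (68.0 to 172.8), 1.16 (66.3 to 148.6) and 1.09 (62.8 to 133.7). The 3 lower ones, also with no gene name, had log2 ratios of -1.52 (179.4 to 62.4), -1.45 (267.0 to 97.8) and -1.08 (109.8 to 51.9). The brightest of all these probe sets, at 1105 in the wild type, is far above the floor of 39.8. For comparison, 42 of the 8133 measured genes were at least 2-fold higher and 53 were at least 2-fold lower, so differences of this size were also found there. No gene is named from the unnamed or several-gene probe sets here.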

How the results depend on the processing

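No paired analysis was possible because each genotype has 1 array and the labels give no replicate numbers, and no array could be left out for the same reason. The counts of 53 genes higher and 56 lower became 126 and 106 with the floor at the 25th percentile, and 18 and 32 at the 60th. They became 9 and 3 at a 3-fold limit, and 394 and 269 at 1.5-fold. They stayed within 1.5 times under median centring, quantile, loess, the pseudocount, the median over probe sets and without _x_at and _s_at probe sets. The genes were not all the same: with the pseudocount (74 higher, 65 lower) only 29 of the 53 and 36 of the 56 were called again. The deposited scale moved nothing, because the arrays already shared it, and says nothing about scaling. Of the list medians under the alternatives, 336 stayed within 0.26, the probe set SD, and 4 did not. The 336 include those on the deposited scale, which could not move. With the 60th percentile floor the G2 and mitosis median was -1.39, where dimmer members have only bounds, and the sex chromosome median was 0.41, where Xist alone was measured. The red blood cell median was 0.24 with the 25th percentile floor and 0.21 with a pseudocount, against -0.19, and the cause was not tested. Both cell cycle lists, glucose sensing and maturity, translocation, ER to Golgi trafficking, alpha and delta cell regulators, mesenchymal genes and immune markers were outside the random range in all 10 alternatives. The deposited scale is 1 of these and could not differ. Ribosomal proteins and lipid synthesis were so in 9, and Schwann and neuronal markers in 5. Ratios of named genes stayed within 0.26 in 936 values, moved further in 26 and reversed in 2. Hip1r reversed to 0.0044 with the median over probe sets. Asb6 reversed to 0.50 without _x_at and _s_at probe sets, where its other probe set stands in. Many of the 936 values could not move, so their number overstates stability. The deposited scale changed nothing, and a floor leaves the ratio of a gene above it on both arrays unchanged. The choice of probe sets cannot change a gene with a single probe set of another type. With the 60th percentile floor, Eif2ak3 has only a bound, so signal over background limits what can be said of dim genes.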

Other observations

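The tests on mesenchymal and endothelial markers, on the number of libraries, on leukocytes of every kind and on other cell types moving alike were chosen after the results were seen. The single genes named in this part were also chosen then. Further genes of chromosome segregation were gathered after the lower cell cycle values were seen, so they are no independent evidence for them. Of 16 measured kinetochore and spindle checkpoint genes on no fixed list, 14 were below equality and 7 were at least 2-fold lower, with a median log2 ratio of -0.51. These 7 were Spc25 (-1.58), Nuf2 (-1.34), Mad2l1 (-1.29), Incenp (-1.28), Cenpk (-1.11), Mis12 (-1.09) and Ndc80 (-1.04), and Ndc80, Nuf2 and Spc25 encode subunits of a complex that binds microtubules. The 2 above equality were Pmf1 (0.34) and Cenpq (0.08), the latter of which changed sign over the scalings (lowest value -0.01). The Reg family of secreted pancreatic proteins, linked to injury and regeneration, was also chosen after the values were seen. Reg2 went from 75.6 to 193.8 (log2 1.36), Reg3d from 60.3 to 129.8 (1.11) and Reg1 from 1799 to 3240 (0.85). Reg1 is also on the acinar list, where Pla2g1b (0.92), Ctrl (0.69), Zg16 (0.67) and Cel (0.46) were higher too. Of 23 measured members of that list, 17 were above equality and 6 below, with a median of 0.08. Reg3b was level at 0.06, and Reg3a, Reg3g and Reg4 were at the floor on both arrays.

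Error of single probe sets was examined on 10 cell cycle genes with a second measured probe set. They were selected for being at least 1.5-fold lower on their brightest one. Their second-brightest probe sets were all below equality, from -0.16 for Cenpf to -1.46 for Rrm2, with a median of -0.54. For these genes this argues against such error as the source of the lower direction. Cell cycle genes with a single measured probe set are not covered. The mesenchymal and endothelial lists were not lower by as much: the lower of their medians was -0.19, against -1.04 for the mitosis list. Both medians were known when this test was chosen. A list median also cannot show the loss of a small dividing part of those cells, so such a loss stays open. The genotype of the pups stays open, because there was 1 library per genotype and any difference between litters, sexes or preparations falls on the same contrast. Which cell type carried these transcripts was not tested.

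The higher myeloid transcripts were set against more neutrophils or their precursors. The 4 neutrophil genes on no other list that were measured on both arrays had a median of 0.27, under the limit of 0.5 set to exclude this. That limit was a poor one, because the rule left out genes at the floor in the wild type: Camp went from 4.3 to 156.3, Ltf from 32.6 to 87.6, Chil3 from 8.6 to 71.2, Mpo from 37.7 to 62.6 and Elane from 36.4 to 56.2. With these and Mmp8, which was at the floor in the knockout instead (46.4 to 36.0), at their bounds, the median of 10 was 0.58 with 9 above equality. A gene at the floor in the wild type only can lie only above equality, so this count is no support. Of the 4 measured genes, Lcn2 was at 1.95, while Fcgr3 (0.32), Mmp9 (0.21) and Itgb2 (0.12) were higher by less. Another 5 (Prtn3, Cd177, Itgam, Cybb and Cxcr2) were at the floor on both arrays and have no ratio. More neutrophils or their precursors stays open, as does the genotype. More leukocytes of every kind by the same factor could not be decided. The immune list without S100a8 and S100a9 had a median log2 ratio of 0.63 with 12 of 13 genes above equality. Those 2 genes were 7.98-fold and 6.44-fold higher, the largest ratios of all measured genes. The other members had to lie below them, so this gap was known when the test was chosen. Macrophage markers of that list ranged from -0.02 for Mrc1 and 0.07 for Csf1r over 0.56 for Cd68, 0.68 for Adgre1, 0.72 for C1qb, 0.86 for Lyz2 and 0.87 for C1qa to at least 1.43 for C1qc, so a smaller increase of such cells stays open.

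For the lower beta cell maturity transcripts, a lower share of beta cells was tested on 9 measured beta cell genes from no other list. Their median was -0.47, between the limits set for and against, with 6 below equality (Hadh -0.43, Nnat -0.71 and Mlxipl -0.67 among them) and 3 above it (Dlk1 0.39, Cltrn 0.32 and Matn2 0.08). A lower share that raises every other cell type alike was set against 2 lists only. The 25th percentile of the alpha and delta cell list (5 genes) lay 0.39 above the 75th percentile of the mesenchymal list (22 genes). These 2 lists did not move alike, but both medians were known when the test was chosen, so it does not decide the question. A lower share, alone or beside other changes of cell composition, cannot be told apart from a change of expression within beta cells, and the genotype stays open. The Ins2 signals, at 69.5% and 74.8% of the array maxima, may be compressed, and a dimmer Iapp probe set (410.5 to 442.8, log2 0.11) was not lower but is a single probe set.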
